A study of Caenorhabditis elegans with 12 samples.

How the data were processed

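RNA from whole Caenorhabditis elegans at the L4 stage was compared in 4 groups of 3 libraries: the wild type N2 and the mutant affl-2(sy975), each with and without heat shock. Per the labels, 250 L4 animals were picked for a plate, sealed with parafilm and kept for 30 min either in a water bath at 33 °C or at 20 °C. Poly(A) RNA was selected, fragmented to about 200 nt on average and sequenced as single reads of 50 nt. The labels speak of each condition in each replicate but do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries. The library kit is one that keeps no strand, and the strand of the reads was not given in the sources used here.

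The deposited tables hold, per the submitters' processing notes, the output of kallisto (version not given in the sources used here) on base calls converted with bcl2fastq 1.8.4, against genome build WBcel235. Each deposited table gives estimated counts, TPM (transcript abundance scaled for length and depth) and effective length for 35862 transcripts. The effective lengths match a mean fragment length of 300 nt given to kallisto. The estimated counts, not all whole numbers, sum to between 18.0 and 22.7 M per library (22.7, 21.2 and 20.6 M in unheated N2, 20.3, 18.6 and 20.8 in heated N2, 18.0, 18.4 and 19.3 in unheated affl-2, and 22.2, 19.8 and 20.5 in heated affl-2). TPM and effective length were used only for the alternative with offsets for average transcript length and for the test on transcript length.

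Here, estimated counts were summed over the transcripts of each gene, giving 22010 genes by sequence name, and rounded. Of these, 21839 were matched to the Ensembl release 115 annotation, and the 171 others, kept under their sequence names, hold 0.0698 to 0.0973% of a library's counts. Between 17743 and 18382 genes were detected per library, and the 10 most abundant genes held 4.10 to 6.69% of the counts. Reads shared by near-identical genes are divided between them by kallisto. Among genes with a mean count above 10, 30 pairs differed by no more than 0.5% in at least 10 of 12 libraries. They include hsp-16.48 with hsp-16.49, pud-2.1 with pud-2.2 and numr-1 with numr-2. hsp-16.1 stood at 0 in all 12 libraries, with the reads of this pair of copies assigned to hsp-16.11.

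Genes with enough counts were kept with filterByExpr by group (minimum count 10), leaving 15386 genes tested and 6624 set aside. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, one quasi-likelihood fit (robust) of the 4 group means over all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 0.147) and quasi-likelihood F tests. The 5 comparisons were heat shock in N2, heat shock in affl-2, affl-2 against N2 without heat shock, affl-2 against N2 after heat shock, and the interaction (the heat shock effect in affl-2 minus that in N2). Adjusted p-values are Benjamini-Hochberg over all genes tested unless they are said to be adjusted over a list alone, and a gene passed at 0.05. Errors of log2 changes are standard errors from the F statistic, and CPM (counts scaled to a common library size) are given as mean ± SD of 3 libraries. Heat-responsive genes were those whose heat shock effect averaged over the genotypes passed with a log2 change beyond 1, a choice that favours neither sign of the interaction. The hsp-16 genes were also summed and tested as 1 gene.

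The comparisons, the alternatives, 28 gene lists written from general knowledge and the rule for naming genes were fixed before the data were examined. Of the listed names, 9 matched no gene symbol and were left out. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, Benjamini-Hochberg over lists within a comparison, and also with an estimated correlation. The naming rule took, per comparison, the 12 genes with the highest and the 12 with the lowest log2 change among genes that passed, had an average log2 CPM of at least 1 and, for comparisons of a pair of groups, had no overlap between groups. It added affl-2, affl-1, hsf-1, all members of the small heat shock protein and HSP70 lists, and up to 4 members with the smallest adjusted p of each other list. Other genes named were chosen after their values were seen, and the text says so. A fold against a group with 0 counts in every library is a lower bound with a floor of 3 counts per library, and no fold is given against a group with 1 to 3 counts.

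The fit was tested on simulated data with the same depth and spread, with 100 genes changed at each size per comparison. At a log2 change of 1 it recovered 74% (heat shock in N2, 15237 genes tested), 72% (heat shock in affl-2, 15239), 76% (genotype without heat shock, 15239), 69% (genotype after heat shock, 15227) and 40% (interaction, 15233). At a log2 change of 2 the shares were 97, 92, 97, 92 and 86%. False calls numbered 14, 3, 7, 9 and 8 and none of the changed genes was called in the wrong direction. Genes were simulated independently around a mean shared by the groups, without batches and with far fewer changes than the real data. The false calls therefore do not give the error rate in the real data. Between replicates, chi-square per gene on the counts was 9.88 to 47.18, so the spread lies well above counting noise.

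The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper quartile scaling in edgeR, no filter on low counts, a minimum count of 50, the replicate number as a block (also with 2 replicate numbers of unheated affl-2 exchanged), only the libraries of the groups compared, transcript length offsets, near-identical copies summed, a test against a 2-fold change, other ways to choose heat-responsive genes and each library left out in turn. The copies summed were hsp-16.1 with hsp-16.11, hsp-16.48 with hsp-16.49 and F44E5.4 with F44E5.5, and other near-identical pairs were left apart. Scaling by library size alone was added after the data were seen. Enrichment of gene families, chosen after the data were seen, used Fisher's exact test over 383 families.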

Results

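The level of affl-2 itself was examined in every library. The labels do not give the sy975 lesion, so no level was predicted and the values cannot check the genotype of a library. affl-2 mRNA stood at 22.2, 25 and 21 CPM in unheated N2 and 25.2, 25.6 and 30.0 CPM in heated N2, against 15.2, 15.4 and 19.6 CPM in unheated affl-2 mutants and 19.2, 16.3 and 17.3 CPM in heated mutants. With TMM scaling every mutant library lay below every N2 library. Without the TMM factors (1.085 and 0.987) unheated affl-2 replicate 3 lay slightly above unheated N2 replicate 3. The mRNA was lower in the mutant by a log2 change of −0.44 ± 0.13 without heat shock (adjusted p = 0.0374) and −0.61 ± 0.13 after it (adjusted p = 0.00544) (3 libraries per group), and transcript of the gene remained in the mutant. Scaling by library size alone moved the median of all genes by 0.183 without heat shock and 0.223 after it. Such a shift makes both differences smaller. The change of affl-2 mRNA with heat shock did not pass in either genotype (0.24 ± 0.13 in N2 and 0.07 ± 0.13 in the mutant, adjusted p = 0.207 and 0.734). Its paralogue affl-1, the gene directly downstream of affl-2 on the same strand, had almost no reads without heat. After heat shock it reached 0.54 ± 0.07 CPM in N2 and 1.43 ± 0.08 CPM in the mutant, a rise in the mutant over N2 of 1.40 ± 0.37 (adjusted p = 0.0171). hsf-1, the gene of the heat shock transcription factor, did not pass in any comparison (61.6 CPM in heated N2 and 56.7 CPM in heated mutants). Where a list has examples beyond those the naming rule gives, they were chosen after their values were seen.

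The response of N2 to 30 min at 33 °C was the first question, and inducible chaperones were among its largest rises. hsp-70 rose from 4.08 ± 2.63 to 2744 ± 282 CPM, a log2 change of 9.4 ± 0.45 (adjusted p = 6.8e-08, 3 libraries per group). The HSP70 genes F44E5.4 and F44E5.5, which lie side by side, rose by 8.07 ± 1.11 and 7.61 ± 0.55, and together reached 15680 ± 1464 CPM. The hsp-16 small heat shock protein genes, summed because copies share reads, went from 20.8 ± 24.3 to 6631 ± 601 CPM (log2 change 8.32, adjusted p = 0.000287). Members seen apart gave 8.92 ± 0.69 (hsp-16.2), 8.98 ± 0.64 (hsp-16.41), 8.10 ± 0.88 (hsp-16.11) and 8.03 ± 0.72 (hsp-16.48 and hsp-16.49, which cannot be told apart).

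Beyond these, hsp-110 rose by 3.26 ± 0.11, the endoplasmic reticulum BiP gene hsp-4 by 2.50 ± 0.15, the constitutive hsp-1 by 1.13 ± 0.10 and the mitochondrial hsp-6 by 0.91 ± 0.09. Of the HSP70 and HSP110 family 7 of 11 members rose and none fell, the same when adjusted over the list alone. The list median was 1.13 (camera adjusted p = 2.6e-19, adjusted p = 0.00827 with an estimated correlation). Among HSP90, HSP40 and their cochaperones 12 of 15 rose, 13 when adjusted over the list alone. The median of the list lay at 0.68 (camera adjusted p = 1.5e-24, adjusted p = 0.00827 with an estimated correlation). They include hsp-90 (1.42 ± 0.11), the HSP40 gene dnj-13 (2.73 ± 0.10) and the BAG-domain genes unc-23 (3.56 ± 0.14) and bag-1 (2.03 ± 0.10). Of the small heat shock proteins 8 of 12 rose, also when adjusted over the list alone, counting the copies hsp-16.48 and hsp-16.49 apart. Steps were smaller for hsp-17 (1.27 ± 0.24) and hsp-43 (0.91 ± 0.13), with none for sip-1 or the hsp-12 genes. Their median was 1.09 (camera adjusted p = 3.1e-06, adjusted p = 0.204 with an estimated correlation). All 8 CCT chaperonin subunits rose, by 0.28 (cct-7) to 0.52 (cct-6), and all 8 when adjusted over the list alone. Their median came to 0.39 (camera adjusted p = 0.00185, adjusted p = 0.744 with an estimated correlation). Under scaling by library size alone the median of all genes moved by −0.182 in this comparison, which makes the CCT rises smaller.

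**Figure D1:**
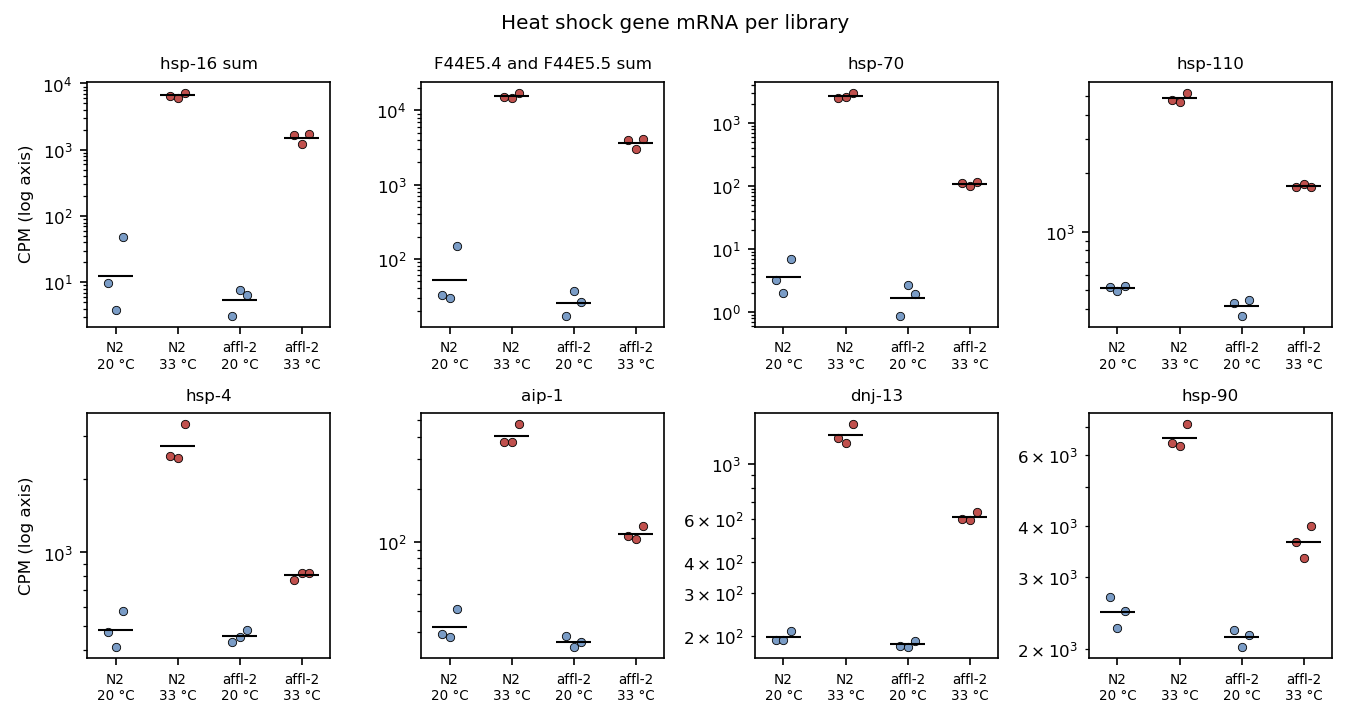
CPM on a log axis for 8 heat shock genes or sums of copies, 1 point per library in each of the 4 groups (N2 and affl-2 at 20 °C and 33 °C), with a line at the geometric mean. Heated affl-2 libraries lay below heated N2 libraries in each panel, for example 110 against 2744 CPM for hsp-70 and 1538 against 6631 CPM for the hsp-16 sum.

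Across all genes heat shock in N2 changed 3314 of 15386, 1465 higher and 1849 lower, with 581 and 603 beyond 2-fold. Autophagy genes rose in 9 of 23 cases and fell in 2, or 11 and 3 when adjusted over the list alone. Their median was 0.20 (0.02 under library size alone, camera adjusted p = 0.00086, adjusted p = 0.0264 with an estimated correlation). The cargo receptor gene sqst-1 (2.94 ± 0.15), atg-2 (1.1 ± 0.11) and lgg-1 (0.90 ± 0.12) were among them. The list of stress transcription factors and HSF-1 regulators had 6 of 16 members higher, with 6 higher and 1 lower when adjusted over the list alone. Across the list the median was 0.11 (−0.07 under scaling by library size alone, camera adjusted p = 0.00168, adjusted p = 0.206 with an estimated correlation). Its largest change was in aip-1 (3.64 ± 0.16), which encodes an AN1 zinc finger proteasome adaptor and not a transcription factor, ahead of pqm-1 (1.87 ± 0.16), xbp-1 (0.68 ± 0.12) and skn-1 (0.48 ± 0.10). In the endoplasmic reticulum unfolded protein response list only 4 of 19 rose, also 4 when adjusted over the list alone, namely hsp-4, xbp-1, ero-1 (0.32 ± 0.09) and the kinase gene pek-1 (2.31 ± 0.09). The median stayed at 0.09 (−0.09 under library size alone, camera adjusted p = 0.00395, adjusted p = 0.894 with an estimated correlation). Muscle genes rose in 5 of 21 cases and fell in 1 (8 and 2 when adjusted over the list alone), led by unc-54 (0.98 ± 0.16), unc-22 (1.04 ± 0.19) and unc-89 (1.00 ± 0.18). The muscle median was 0.17 (−0.02 under library size alone, camera adjusted p = 0.0272, adjusted p = 0.915 with an estimated correlation).

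The neuronal and intestinal lists passed at the preset correlation only, with more members called lower than higher. Of 27 neuronal genes 11 fell and 1 rose, or 14 and 1 when adjusted over the list alone, including synaptic snt-1 (−1.02 ± 0.13), rab-3 (−0.99 ± 0.14) and the glutamate transporter gene eat-4 (−1.16 ± 0.17). The list median was −0.42 (camera adjusted p = 0.0108, adjusted p = 0.915 with an estimated correlation). Of 23 intestinal genes 7 fell and 1 rose, or 10 and 1 when adjusted over the list alone, including the peptide transporter gene pept-1 (−1.35 ± 0.13), pho-1 (−0.88 ± 0.13) and the GATA factor gene elt-2 (−0.53 ± 0.14). The desaturase gene fat-6 rose (0.95 ± 0.20). The midpoint of the list was −0.27 (camera adjusted p = 0.00998, adjusted p = 0.915 with an estimated correlation). Among the 12 largest falls under the naming rule were those of C40H1.7 (−3.37 ± 0.59), the astacin protease gene nas-27 (−3.26 ± 0.40), fbxa-180 (−2.85 ± 0.27), asp-13 (−2.54 ± 0.17), folt-1 (−2.46 ± 0.17) and the amine-gated channel gene lgc-55 (−2.45 ± 0.23). Among the largest rises were genes hardly read at 20 °C. F59H6.5 had 0 reads in unheated N2 and 8015 after heat shock (at least 1089-fold higher), and sri-39 had 0 and 414 (at least 56.4-fold higher). The genes dct-10, R11A5.3 and Y38H6C.8 rose by 9.2 ± 0.34, 8.83 ± 0.25 and 8.78 ± 0.35.

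The other lists did not pass as lists in heated N2. The mitochondrial unfolded protein response had 2 of 14 higher (hsp-6 and hsp-60, camera adjusted p = 0.106), and oxidative and xenobiotic stress genes 4 of 21, led by ugt-13 (3.89 ± 0.16) and gst-7 (1.08 ± 0.12, camera adjusted p = 0.0643). The intracellular pathogen response had 1 of 15 higher and 2 lower (pals-22 and pals-25, camera adjusted p = 0.818), antimicrobial genes 2 and 1 of 23 (0.759), metal response genes 3 and 1 of 8 (0.273), and DAF-16 class genes 2 and 2 of 19 (0.687). In the same order, pharynx genes had 2 and 0 of 12 (camera adjusted p = 0.261), sperm genes 2 and 1 of 45 (0.687), molting genes 2 and 2 of 26 (0.723), and col- collagens 4 and 2 of 133 (0.205). Proteasome subunits had only rpn-3 higher among 32 (1.26 ± 0.09, camera adjusted p = 0.143), transcription elongation genes 3 of 22 higher (0.143), germline genes 1 of 24 higher (0.143) and mitochondrially encoded mRNAs 3 of 11 lower (0.261). No ribosomal protein, vitellogenin, oocyte or body-shape collagen gene passed (camera adjusted p = 0.305, 0.725, 0.0545 and 0.462).

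The same heat shock in affl-2 mutants, the next question, again raised the chaperones. hsp-70 rose by 5.92 ± 0.42 (1.81 ± 0.89 to 110 ± 7.31 CPM, adjusted p = 3.2e-06, 3 libraries per group), the hsp-16 sum by 8.06 (5.76 ± 2.33 to 1538 ± 285 CPM, adjusted p = 0.000441) and F44E5.5 by 7.45 ± 0.55. hsp-110 rose by 2.06 ± 0.10, dnj-13 by 1.72 ± 0.10, unc-23 by 2.81 ± 0.13, hsp-4 by 0.83 ± 0.14 and hsp-1 by 0.36 ± 0.10. In all 3300 genes changed, 1637 higher and 1663 lower, with 477 and 596 beyond 2-fold. When only the 6 compared libraries were fitted, heat shock changed 3667 genes in N2 and 2331 in affl-2, and a test for changes beyond 2-fold gave 401 and 265. Genes higher in both genotypes numbered 915 (155.9 by chance, 11 in opposite directions) and genes lower in both 1153 (199.8 by chance, 1 opposite), and these comparisons share no library. The chance counts take every gene as equally likely to be called. Both comparisons use the same spread per gene, so the excess over chance is not a test. Over all genes the heat shock effects correlated with a Pearson coefficient of 0.787 (0.485 without the low-count filter).

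By list, 7 of 11 HSP70 and HSP110 genes rose in the mutant, with 7 higher and 1 lower when adjusted over the list alone. The median of the list lay at 0.36 (camera adjusted p = 1.4e-08, adjusted p = 0.0762 with an estimated correlation). Of HSP90, HSP40 and cochaperone genes 12 of 15 rose, 13 when adjusted over the list alone. These members had a median of 0.57 (camera adjusted p = 1.2e-18, adjusted p = 0.04 with an estimated correlation). Small heat shock proteins passed in 5 of 12 cases, all hsp-16 genes with the copies hsp-16.48 and hsp-16.49 counted apart, and also 5 when adjusted over the list alone (median 0.22, 0.08 under library size alone, camera adjusted p = 9.8e-05, adjusted p = 0.266 with an estimated correlation). All 8 CCT genes rose, by 0.35 (cct-7) to 0.57 (cct-6), also when adjusted over the list alone (camera adjusted p = 9.8e-05, adjusted p = 0.588 with an estimated correlation). Ribosomal protein genes rose in 33 of 78 cases and 58 when adjusted over the list alone, with rps-2 at 0.48 ± 0.12 and rpl-4 at 0.45 ± 0.11. Their median was 0.37 (camera adjusted p = 1.4e-08, adjusted p = 0.843 with an estimated correlation). Under library size alone the median of all genes moved by −0.142 in this comparison, which makes the ribosomal and CCT rises smaller. Muscle genes rose in 10 of 21 cases, 12 when adjusted over the list alone, with unc-54 at 1.01 ± 0.16 and myo-3 at 1.05 ± 0.13. The list passed (camera adjusted p = 0.000395, adjusted p = 0.793 with an estimated correlation). Autophagy genes rose in 10 of 23 cases and fell in 1, or 12 and 2 when adjusted over the list alone, with bec-1 at 0.99 ± 0.10 and sqst-1 at 1.05 ± 0.14. As a list they passed (camera adjusted p = 0.00466, adjusted p = 0.0762 with an estimated correlation).

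Further lists passed in the heated mutant. Proteasome subunits had 3 of 32 higher, led by rpn-3 at 1.28 ± 0.09, and 1 when adjusted over the list alone (median 0.17, 0.03 under library size alone, camera adjusted p = 0.00466, adjusted p = 0.843 with an estimated correlation). Body-shape collagens had 4 of 21 higher and 1 lower, the same when adjusted over the list alone (median 0.81, camera adjusted p = 0.0164, adjusted p = 0.843 with an estimated correlation). dpy-13 rose by 0.93 ± 0.25 and bli-6 by 0.72 ± 0.21, while lon-3 fell by 1.30. Vitellogenins fell in 2 of 6 cases, vit-1 (−0.86 ± 0.21) and vit-3 (−0.66 ± 0.19), and 4 when adjusted over the list alone (median −0.61, camera adjusted p = 0.0143, adjusted p = 0.843 with an estimated correlation). Intestinal genes fell in 5 of 23 cases with 1 higher, also when adjusted over the list alone (camera adjusted p = 0.00911, adjusted p = 0.843 with an estimated correlation), among them pept-1 (−1.06 ± 0.12). The oocyte list passed as a list (median −0.48, camera adjusted p = 0.00466, adjusted p = 0.843 with an estimated correlation) with only the yolk receptor gene rme-2 lower (−0.82 ± 0.26) and none when adjusted over the list alone. Stress transcription factor genes were higher in 5 of 16 cases and lower in 1, or 5 and 2 when adjusted over the list alone (median 0.15, 0.01 under library size alone, camera adjusted p = 0.0364, adjusted p = 0.588 with an estimated correlation). The other lists did not pass as lists (camera adjusted p from 0.0571 for molting genes to 0.942 for the pathogen response), although 8 of 27 neuronal genes fell and 4 rose, and 12 of 133 col- collagens rose and 5 fell. Among the 12 largest falls under the naming rule were those of pqn-91 (−2.97 ± 0.69), asp-13 (−2.84 ± 0.17), fbxa-180 (−2.56 ± 0.25), nas-27 (−2.53 ± 0.45), acp-6 (−2.45 ± 0.33) and the nuclear receptor gene nhr-114 (−2.32 ± 0.14).

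Whether the mutant responded differently was tested by the interaction, which 110 genes passed, 103 with a weaker rise or a stronger fall in affl-2 and 7 the other way (216 genes by DESeq2). With the exchanged replicate numbers as a block 221 genes passed, 183 below 0 and 38 above. hsp-70 rose less in the mutant (−3.49 ± 0.56, adjusted p = 0.0131, 3 libraries per group). For hsp-70, interaction of genotype and heat shock did not pass without unheated affl-2 replicate 2 (−3.11, adjusted p = 0.0591) or heated affl-2 replicate 2 or 3 (−3.48 and −3.53, adjusted p = 0.0774 and 0.0502). hsp-4 (−1.67 ± 0.20, adjusted p = 0.00044), hsp-110 (−1.2 ± 0.14, 0.000364), hsp-1 (−0.78 ± 0.14, 0.0151) and hsp-6 (−0.65 ± 0.13, 0.0257) also rose less. Thus 5 of 11 HSP70 and HSP110 genes passed, also when adjusted over the list alone. Across the list the median was −0.65 (camera adjusted p = 4e-15, adjusted p = 0.0292 with an estimated correlation). Outside that family the same held for dnj-13 (−1.01 ± 0.13), aip-1 (−1.57 ± 0.20), sqst-1 (−1.88 ± 0.20) and ugt-13 (−2.13 ± 0.21). hsp-90 was short of passing (−0.64 ± 0.15, adjusted p = 0.087), as were unc-23 (−0.75 ± 0.17, 0.0754) and bag-1 (−0.61 ± 0.14, 0.0624). The hsp-16 sum gave −0.26 (adjusted p = 0.98), with the 3 unheated N2 libraries spread from 3.90 to 48.7 CPM, and left open whether its induction differed. CCT genes gave interactions of 0.00 (cct-5) to 0.08 (cct-4), none passing (camera adjusted p = 0.641).

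Under the naming rule the largest interactions belonged to genes that rose in N2 from low levels, between 0 (sri-39) and 4.08 CPM (hsp-70). Y38H6C.8 reached 37 ± 2.68 CPM in heated N2 and 1.64 ± 0.21 CPM in heated mutants (interaction −6.69 ± 0.63, adjusted p = 4.5e-05). C25F9.2 reached 78 and 1.96 CPM (−5.75 ± 0.51), E01G4.5 54.6 and 3.30 CPM (−4.98 ± 0.39), dct-10 77.4 and 4.79 CPM (−4.60 ± 0.79), and Y17D7C.3 138 and 13.3 CPM (−3.64 ± 0.25). R11A5.3 (−3.01 ± 0.44), Y75B8A.39 (−5.04 ± 0.80), Y53G8AL.1 (−2.64 ± 0.22) and ador-1 (−2.55 ± 0.50) followed the same course, and Y46H3A.5, which lies near hsp-16.2 and hsp-16.41 on the chromosome, gave −2.84 ± 0.35. sri-39 had 414 reads in heated N2 and 31 in heated mutants, from 0 and 7 without heat. E01G4.5 rose by 5.31 ± 0.28 in N2, while its change in the mutant did not pass (0.33 ± 0.27, adjusted p = 0.419). Chosen after their values were seen, the glutathione transferase gene gst-36 (−2.19 ± 0.19), the chromatin remodeller gene nurf-1 (−1.74 ± 0.17), the demethylase gene jmjd-3.3 (−1.50 ± 0.31) and the TGF-beta ligand gene daf-7 (−1.66 ± 0.31) also passed. With heat shock daf-7 rose in N2 (0.69 ± 0.21) and fell in the mutant (−0.96 ± 0.23). In the opposite direction R03D7.2 (1.85 ± 0.25), Y105C5A.1 (1.19 ± 0.19), Y67D8C.9 (1.15 ± 0.24) and the dopamine receptor gene dop-2 (1.08 ± 0.21) fell in N2 with no fall passing in the mutant. C37H5.14 (1.07 ± 0.20) rose in the mutant with no rise passing in N2, and Y54G2A.24 (1.17 ± 0.25) fell less in the mutant. The last of the 7, F28B12.6, read too little for the naming rule and named after its value was seen, gave 3.2 ± 0.65 (adjusted p = 0.0341).

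**Figure D2:**
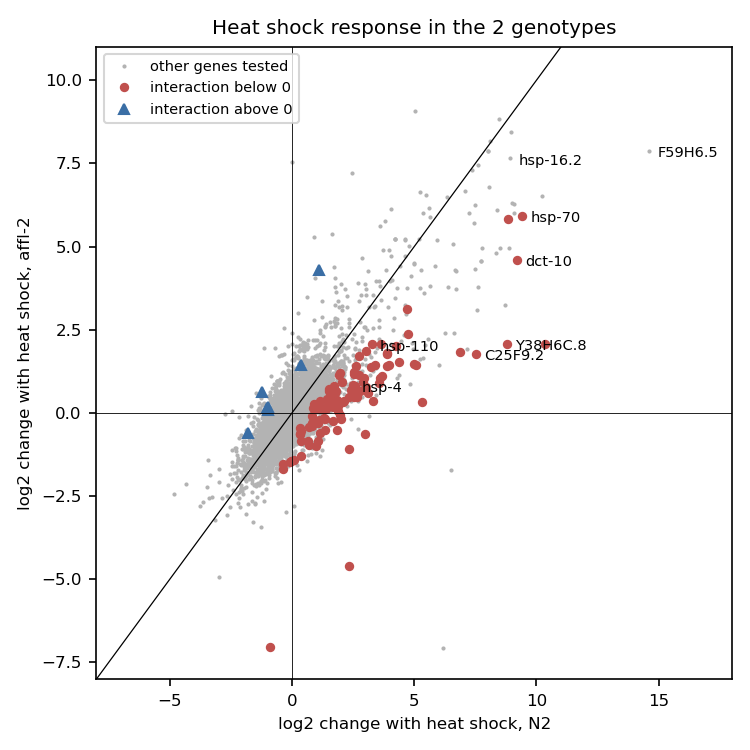
Log2 change with heat shock in N2 (horizontal) against that in affl-2 (vertical), 1 point per gene tested, with the diagonal marking equal responses. Red circles are the 103 genes with an interaction below 0 and blue triangles the 7 above 0, and the red circles lie below the diagonal, mostly among genes that rose in N2.

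Taken as a group, 564 genes rose and 596 fell with heat shock on average over the genotypes. The rising genes had a median log2 change of 1.90 in N2 and 1.46 in affl-2, with a median interaction of −0.335 (SD over replicate numbers 0.104) and 362 of them (64.2%) below 0. Of these genes 60 passed as weaker in the mutant and 1 as stronger, or 25.2% and 3.4% when adjusted over the list alone. The falling genes had medians of −1.28 and −1.31, a median interaction of 0.009 (SD 0.216), 1 gene weaker and 2 stronger. Without unheated affl-2 replicate 3 the median interaction of the rising genes was −0.179, with 58 stronger when adjusted over the list alone, against 11 without heated N2 replicate 2 and 12 without unheated N2 replicate 2. The size of that median also moved with the way the genes were chosen, and choosing them in affl-2 alone turned it to 0.129.

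Several lists passed the interaction test as lists with few or no single genes. The mitochondrial unfolded protein response passed under both correlations, with hsp-6 and the transporter gene haf-1 (−1.2 ± 0.23) passing and 3 of 14 when adjusted over the list alone. Their median came to −0.20 (camera adjusted p = 0.000184, adjusted p = 0.0292 with an estimated correlation). Since hsp-6 is also in the HSP70 and HSP110 list, these lists are not separate evidence. HSP90, HSP40 and cochaperones had dnj-13 passing and 4 of 15 when adjusted over the list alone (median −0.12, camera adjusted p = 6e-05, adjusted p = 0.397 with an estimated correlation). Small heat shock proteins had none and 2 of 12. The midpoint of the list was −0.18 (camera adjusted p = 0.0195, adjusted p = 0.594 with an estimated correlation). Stress transcription factors (camera adjusted p = 0.011, adjusted p = 0.397 with an estimated correlation), the endoplasmic reticulum response (0.011 and 0.701 in the same order) and oxidative stress genes (0.011 and 0.701) had aip-1, hsp-4, ugt-13 and gst-7 as their only passing members. In ribosomal proteins (median 0.29, camera adjusted p = 1.7e-11, adjusted p = 0.701 with an estimated correlation), mitochondrially encoded mRNAs (0.49, 0.000897 and 0.594), sperm genes (0.24, 0.00033 and 0.701), and neurons (0.22, 0.011 and 0.701) no gene passed. The same held for body-shape collagens (median 0.43, 0.0195 and 0.8), molting genes (0.33, 0.0212 and 0.8) and vitellogenins (−0.52, 0.00133 and 0.594). The remaining lists did not pass as lists.

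How the mutant strain differed from N2 in animals kept at 20 °C was asked next. Here 2150 genes differed, 1029 higher and 1121 lower in affl-2, with 347 and 448 beyond 2-fold. The count was 1422 without unheated N2 replicate 1, 1220 without unheated N2 replicate 3 and 1228 without unheated affl-2 replicate 2, and under scaling by library size alone 2737 were higher and 649 lower. With the exchanged replicate numbers as a block it was 3604. Yolk protein mRNA was lower throughout. vit-2 stood at 5731 CPM in N2 and 2220 CPM in the mutant (−1.37 ± 0.19, adjusted p = 0.00042, 3 libraries per group), and vit-5 at 2180 and 443 CPM (−2.30 ± 0.29). All 6 vitellogenins passed, also when adjusted over the list alone. These members had a median of −1.53 (camera adjusted p = 1.5e-14, adjusted p = 0.255 with an estimated correlation). Cuticle collagens were lower too. Of 21 collagens with body-shape phenotypes 14 passed and all 21 did when adjusted over the list alone, among them bli-6 (−1.71 ± 0.22), rol-1 (−1.47 ± 0.26), sqt-3 (−1.43 ± 0.37) and lon-3 (−1.87 ± 0.37). The much larger but scattered differences of dpy-7 and dpy-10 fell short over all genes (−2.94 ± 1.02 and −3 ± 1.00, adjusted p = 0.0947 and 0.0827). The body-shape list had a median of −1.71 (camera adjusted p = 4.1e-14, adjusted p = 0.315 with an estimated correlation). Of 133 col- collagens 60 were lower and 5 higher, or 76 and 9 when adjusted over the list alone, with col-90 at −2.31 ± 0.23 and col-182 at −2.68 ± 0.27, and col-95 going the other way at 3 ± 0.47. The list median was −0.66 (camera adjusted p = 6.4e-18, adjusted p = 0.315 with an estimated correlation). Molting genes passed as a list, with wrt-4, nas-37 and mlt-8 lower, and 2 when adjusted over the list alone. The median of the list lay at −0.66 (camera adjusted p = 0.00442, adjusted p = 0.739 with an estimated correlation).

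The machinery of protein synthesis and turnover was lower by small amounts in many genes at once. Ribosomal proteins were lower in 47 of 78 cases, 68 when adjusted over the list alone, such as rps-29 (−0.64 ± 0.11) and rpl-4 (−0.46 ± 0.11). Their median came to −0.41 (−0.23 under library size alone, camera adjusted p = 3.8e-17, adjusted p = 0.515 with an estimated correlation). Proteasome subunits were lower in 20 of 32 cases, 31 when adjusted over the list alone, such as pbs-1 (−0.43 ± 0.09) and rpn-7 (−0.38 ± 0.09). Their median was −0.31 (−0.12 under library size alone, camera adjusted p = 1.1e-09, adjusted p = 0.515 with an estimated correlation). Germline genes were lower in 7 of 24 cases, 9 when adjusted over the list alone, with fbf-2 at −0.64 ± 0.11, pgl-1 at −0.53 ± 0.13 and glh-1 at −0.48 ± 0.13. Their median was −0.28 (−0.09 under library size alone, camera adjusted p = 9.7e-05, adjusted p = 0.643 with an estimated correlation).

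Lists tied to longevity, metals and defence also passed in the unheated mutant, with more members called lower than higher. DAF-16 class genes passed in 9 of 19 cases as lower and 2 as higher, or 12 and 2 when adjusted over the list alone. Across the list the median was −0.93 (camera adjusted p = 5.6e-07, adjusted p = 0.273 with an estimated correlation). Besides vit-2, vit-5 and lys-7 they included the glyoxylate cycle gene icl-1 (−1.50 ± 0.13), dod-3 (−2.97 ± 0.43), dod-17 (−1.19 ± 0.15), gst-4 (−0.93 ± 0.15) and ftn-1 (−1.09 ± 0.27), against a higher level of fat-7 (1.25 ± 0.36) and the small heat shock protein gene sip-1 (0.92 ± 0.12). The DAF-16 list does not separate its members by the direction in which DAF-16 acts on them, so its median does not measure DAF-16 activity. It also shares members, such as vit-2, vit-5, lys-7 and ftn-1, with other lists here and is not separate evidence. Antimicrobial genes were lower in 9 of 23 cases and higher in 2, the same when adjusted over the list alone, with irg-4 at −2 ± 0.29, lys-2 at −1.42 ± 0.24 and lys-7 at −1.29 ± 0.23. The midpoint of the list was −0.30 (camera adjusted p = 0.00201, adjusted p = 0.643 with an estimated correlation). Metal response genes were lower in 4 of 8 cases, 5 when adjusted over the list alone, counting the copies numr-1 and numr-2 apart. These members had a median of −0.66 (camera adjusted p = 0.00703, adjusted p = 0.515 with an estimated correlation). Among the 12 genes lowest under the naming rule were pud-1.2 (251 ± 138 CPM in N2 and 2.19 ± 0.59 CPM in the mutant, −6.84 ± 0.70) and its relatives pud-2.1, pud-3 and pud-4 (−5.96 ± 0.61, −5.09 ± 0.95 and −5.78 ± 0.87). They also included Y71G12B.18 (−6.43 ± 0.54), D1014.6 (−6.34 ± 0.58), BE0003N10.6 (−5.91 ± 0.39), the acyl-CoA dehydrogenase gene acdh-2 (100 ± 14.4 to 2.94 ± 1.36 CPM, −5.09 ± 0.26) and the lipase gene lips-6 (−4.18 ± 0.35). Chosen after its value was seen, the acyl-CoA synthetase gene acs-2 was lower, at −2.68 ± 0.22. On the higher side T08G11.2 had 1383 reads in the 3 mutant libraries and 1 in N2, C07G1.7 was higher by 4.78 ± 0.51, fbxa-193 by 3.92 ± 0.37 and pals-32 by 2.27 ± 0.27.

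No heat shock list passed at 20 °C. Small heat shock proteins had sip-1 and hsp-43 higher (2 of 12, and 2 each way when adjusted over the list alone, median −0.65, camera adjusted p = 0.679). The hsp-16 sum was 5.76 CPM in the mutant against 20.8 CPM in N2, a log2 change of −1.85 that did not pass (adjusted p = 0.164) but did without unheated N2 replicate 2 (−2.34, adjusted p = 0.0379). Without unheated N2 replicate 3, which alone stood at 48.7 CPM, it was −0.27 (adjusted p = 0.715). HSP70 and HSP110 genes had hsp-6 higher and F44E5.5 lower (1 each of 11, or 1 and 2 when adjusted over the list alone, camera adjusted p = 0.197). Summed with its copy F44E5.4, the genotypes overlapped (29.4 to 149 CPM in N2 and 17.2 to 36.6 CPM in the mutant). Unheated N2 replicate 3 again stood highest in that sum. HSP90, HSP40 and cochaperones had none (0.539) and CCT only cct-8 lower (0.131). The unfolded protein response lists (1 higher and 2 lower of 19, and 1 higher of 14), oxidative stress genes (2 and 5 of 21) and the pathogen response (3 and 1 of 15) did not pass as lists (camera adjusted p = 0.335, 0.197, 0.169 and 0.131). Autophagy (2 higher of 23) and stress factors (zip-2 lower) did not either (0.0942 and 0.871). Nor did elongation (affl-2 lower among 22), mitochondrially encoded mRNAs, sperm, oocyte, muscle, pharynx, intestine or neuronal genes (camera adjusted p = 0.112, 0.679, 0.102, 0.55, 0.0551, 0.165, 0.0942 and 0.55). In the intestine list the cathepsin genes cpr-1, cpr-4, cpr-5 and cpr-6 were lower (−1.24 to −1.04) while fat-5, fat-7 and gtl-1 were higher, so its members parted.

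**Figure D3:**
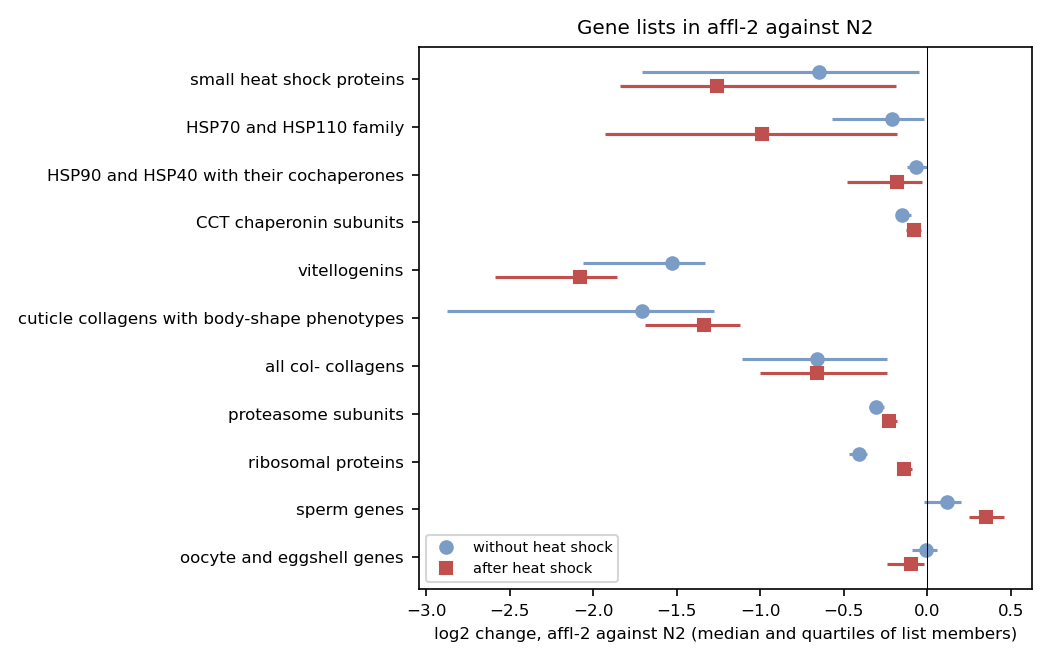
Log2 change of affl-2 against N2 for the members of 11 gene lists, without heat shock (blue circles) and after it (red squares), with the median as the point and the quartiles as the line. Vitellogenins (medians −1.53 and −2.08) and body-shape collagens (−1.71 and −1.34) lie furthest left and HSP70 genes move left with heat (−0.21 to −0.99), while under scaling by library size alone the points of CCT, HSP90 with HSP40 and oocyte genes in both states, and of ribosomal proteins after heat shock, lie above 0.

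After heat shock, where the question was which mRNA the mutant lacked once challenged, 3034 genes differed, 1561 higher and 1473 lower in affl-2, with 352 and 600 beyond 2-fold. The count was 1763 and 1726 without heated N2 replicates 1 and 2, and 1475 and 1947 without heated affl-2 replicates 1 and 3. Upper-quartile scaling gave 2495 higher and 1136 lower, and library size alone 4868 and 831. With the exchanged replicate numbers as a block 5155 genes differed. hsp-70 was lower (−4.64 ± 0.36, 110 against 2744 CPM, adjusted p = 8.8e-06, 3 libraries per group), as were hsp-110 (−1.50 ± 0.10), hsp-4 (−1.77 ± 0.14), hsp-1 (−0.99 ± 0.10) and F44E5.5 (−2.10 ± 0.42). Its copy F44E5.4 was not called, though the sum of the copies did not overlap (3014 to 4073 against 14680 to 17360 CPM). Thus 5 of 11 HSP70 and HSP110 genes were lower, 8 when adjusted over the list alone. Their median was −0.99 (camera adjusted p = 3.3e-10, adjusted p = 0.0677 with an estimated correlation). Among small heat shock proteins 6 of 12 were lower and sip-1 higher, or 7 and 1 when adjusted over the list alone, with hsp-16.2 at −3.08 ± 0.50, hsp-16.41 at −3 ± 0.47 and hsp-17 at −1.22 ± 0.24. hsp-16.48 with hsp-16.49 gave −1.84 ± 0.53 (adjusted p = 0.039, lost without any 1 of the heated libraries). These copies counted as separate members of the list, also in camera, and the list was not tested with them summed. The list median was −1.26 (camera adjusted p = 0.0496, adjusted p = 0.523 with an estimated correlation). The hsp-16 sum was 1538 ± 285 CPM against 6631 ± 601 CPM, a log2 change of −2.11 that did not pass (adjusted p = 0.0697). Even so, the heated groups did not overlap (1209 to 1711 and 6077 to 7270 CPM). With replicate numbers as a block the adjusted p of the sum was 0.0632 as titled and 0.0403 exchanged. The fit takes 1 spread per gene from all 4 groups, and without replicate 2 or 3 of unheated N2 the adjusted p was 0.0207 and 0.00148, within a range of 0.00148 to 1 over all alternatives.

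hsp-90 (−0.85 ± 0.11), dnj-13 (−1.11 ± 0.10), unc-23 (−0.71 ± 0.12) and bag-1 (−0.68 ± 0.10) were the 4 of 15 lower in their list, 7 when adjusted over the list alone. Across the list the median was −0.18 (0.04 under library size alone, camera adjusted p = 0.000573, adjusted p = 0.43 with an estimated correlation). In the endoplasmic reticulum response 4 of 19 were lower, the same when adjusted over the list alone (hsp-4, xbp-1, pdi-2 and the choline kinase gene ckb-2, median −0.06, 0.16 under library size alone, camera adjusted p = 0.00982, adjusted p = 0.529 with an estimated correlation). Oxidative stress genes were lower in 6 of 21 cases and higher in 1, or 8 and 2 when adjusted over the list alone, with ugt-13 at −1.61 ± 0.14 and gst-4 at −1.48 ± 0.16. The median of oxidative stress genes lay at −0.18 (0.04 under library size alone, camera adjusted p = 0.00267, adjusted p = 0.523 with an estimated correlation). aip-1 (−1.87 ± 0.14), xbp-1 (−0.55 ± 0.12), pqm-1 (−0.51 ± 0.15) and zip-2 (−0.44 ± 0.12) were lower among stress factors, though the list did not pass (camera adjusted p = 0.105). sqst-1 was lower, at −1.25 ± 0.14 against 3 autophagy genes that were higher (camera adjusted p = 0.617), and hsp-60 and haf-1 were lower in the mitochondrial response (camera adjusted p = 0.168).

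Most of the difference seen at 20 °C persisted. Genes lower in both states numbered 732 (107.3 by chance, none in opposite directions) and genes higher in both 611 (104.4 by chance, 10 opposite), from libraries that are not shared. These chance counts have the same limit as those for heat shock. Vitellogenins were lower in 6 of 6 cases, also when adjusted over the list alone, with vit-2 at −1.88 ± 0.19 and vit-5 at −2.82 ± 0.30. Their median came to −2.08 (camera adjusted p = 5.3e-18, adjusted p = 0.0677 with an estimated correlation). Body-shape collagens were lower in 11 of 21 cases, 12 when adjusted over the list alone. The midpoint of the list was −1.34 (camera adjusted p = 9.7e-07, adjusted p = 0.523 with an estimated correlation). Among col- collagens 60 of 133 were lower and 1 higher, or 70 and 3 when adjusted over the list alone (camera adjusted p = 2.4e-13, adjusted p = 0.43 with an estimated correlation). DAF-16 class genes (10 of 19 lower and 2 higher, 11 and 3 when adjusted over the list alone, camera adjusted p = 7.1e-07, adjusted p = 0.131 with an estimated correlation) included icl-1 at −2.08 ± 0.14. Metal response genes (4 of 8 lower, 6 when adjusted over the list alone, camera adjusted p = 4.3e-05, adjusted p = 0.36 with an estimated correlation) included ftn-1 at −1.25 ± 0.28. Antimicrobial genes (10 of 23 lower and 2 higher, the same when adjusted over the list alone, camera adjusted p = 0.000966, adjusted p = 0.523 with an estimated correlation) included lys-2 at −1.66 ± 0.24. Germline genes (9 of 24 lower, 15 when adjusted over the list alone, camera adjusted p = 3.9e-05, adjusted p = 0.523 with an estimated correlation) included pgl-1 at −0.61 ± 0.13. pud-1.2 (−6.36 ± 0.69), acdh-2 (−5.59 ± 0.28) and C09B8.4 (−5.52 ± 0.23) were again far lower, now with C25F9.2 (−5.30 ± 0.24) and pqn-91 (−5.21 ± 0.57). On the higher side were C07G1.7 (5.36 ± 0.58), fbxa-193 (2.92 ± 0.34) and dod-21 (2.89 ± 0.43).

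The proteasome and ribosomal lists passed as they did at 20 °C, with fewer members called. Proteasome subunits were lower in 8 of 32 cases, 19 when adjusted over the list alone (median −0.23, −0.01 under library size alone, camera adjusted p = 6.9e-05, adjusted p = 0.523 with an estimated correlation). No ribosomal protein gene passed in the heated animals. These members had a median of −0.14 (0.09 under library size alone, camera adjusted p = 0.0176, adjusted p = 0.768 with an estimated correlation). Sperm genes were higher in 12 of 45 cases, 25 when adjusted over the list alone, with msd-1 at 0.73 ± 0.18 and ssq-3 at 0.58 ± 0.13. Their median was 0.35 (camera adjusted p = 2.7e-05, adjusted p = 0.523 with an estimated correlation). Mitochondrially encoded mRNAs were higher in 2 of 11 cases, 4 when adjusted over the list alone. Their median was 0.46 (camera adjusted p = 0.0496, adjusted p = 0.572 with an estimated correlation). CCT (only cct-8 lower), the pathogen response, elongation, oocyte, molting, muscle, pharynx, intestine and neuronal genes did not pass as lists (camera adjusted p = 0.3, 0.267, 0.0706, 0.258, 0.3, 0.395, 0.0623, 0.24 and 0.22). The genotype effects without and after heat shock correlated with a Pearson coefficient of 0.68 over all genes.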

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

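The split test of the interaction and the tests of scaling and of weaker heating for the reduced induction were chosen after the result was seen, as were those of scaling and of developmental timing for the collagens and vitellogenins, and the other tests were set before the data were examined.

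Every result in this paragraph stood out because the effect of heat shock differed between N2 and affl-2 by the interaction test. It called 110 genes, 103 of them below 0. Values above 0 belonged to R03D7.2 (1.85), Y105C5A.1 (1.19), Y54G2A.24 (1.17), Y67D8C.9 (1.15), dop-2 (1.08) and C37H5.14 (1.07). The last gene above 0, F28B12.6 (3.2, adjusted p = 0.0341), lay below the read level of the naming rule and was named after its value was seen. The largest values below 0 under the naming rule were sri-39 (−8.27, fitted from 0 reads in unheated N2 and so without a lower bound), Y38H6C.8 (−6.69), C25F9.2 (−5.75), Y75B8A.39 (−5.04) and E01G4.5 (−4.98). Next came dct-10 (−4.6), Y17D7C.3 (−3.64), hsp-70 (−3.49), R11A5.3 (−3.01), Y46H3A.5 (−2.84), Y53G8AL.1 (−2.64) and ador-1 (−2.55). Among chaperones and stress genes hsp-4 (−1.67), aip-1 (−1.57), hsp-110 (−1.2), dnj-13 (−1.01), hsp-1 (−0.78), hsp-6 (−0.65) and sqst-1 (−1.88) passed. The lists of HSP70 and HSP110 genes (median −0.65) and of the mitochondrial unfolded protein response (median −0.2) passed under both correlations. Both lists hold hsp-6, so they are not separate evidence.

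The genotype names were exchanged among the libraries within each treatment in a limma fit from which effects shared by both treatments or both genotypes had been taken out, since otherwise genotype differences would enter the spread of the other splits. Of 100 drawn splits, the real one included, 2 called at least as many genes as the real split (110 in this fit too). The effects taken out were those of the real groups, which may favour the real split, and the splits ignored the replicate numbers. This share therefore does not exclude chance. The highest other count was 591 genes, in a split that exchanged libraries in both treatments, and its cause was not tested. The next highest was 11. For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. The real splits, fitted on their 6 libraries, called 3667 genes for heat shock in N2, 2331 for heat shock in affl-2, 1633 for the genotypes without heat shock and 2828 after it, and the highest other split called 0. Each other split mixes the real groups, so the real difference enters its spread and few calls could arise. The 0 therefore lends no support.

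The first pattern weighed was the weaker rise of heat-induced genes in affl-2, with a median interaction of −0.335 over 564 genes, of which 362 (64.2%) lay below 0. A scaling difference moves rising and falling genes alike, yet their median interactions differed by −0.343 (SD over replicate numbers 0.113), which argues against scaling as the whole cause. If falls scale with heat, which was not tested, less heat in the mutant plates would shrink them too. The ratio of the median falls, affl-2 over N2, was 1.023 (0.964 to 1.106 with any 1 library left out), against 0.768 for the rises (0.741 to 0.919). Over the falling genes the heat shock changes of the genotypes correlated with a Pearson coefficient of only 0.267 (0.682 over the rising genes). Weaker heating of the mutant plates is therefore not excluded. Transcript length was not related to the interaction (Spearman rho 0.008, permutation p = 0.842), while the level reached after heat shock was weakly related (rho −0.163, permutation p = 0.00013), between the bounds set beforehand. The permutations take genes as independent, so these p-values do not measure the spread between libraries. The level reached may account for a part. An effect of the affl-2 mutation stays open beside that, as does any other difference between the strains, since 1 mutant strain was compared with N2.

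The second pattern weighed was the induction of little known genes beside strongly induced ones, such as Y17D7C.2 downstream of Y17D7C.3. Reads running past the end of induced genes would favour downstream neighbours. Within 5 kb of 14 strongly induced genes, 2 of 5 downstream neighbours (40%) and 3 of 5 upstream neighbours (60%) were induced, against 3.6% of other genes (Fisher exact p = 1), with 2 genes that lay on both sides left out. The bound set beforehand, a downstream share no higher than the upstream one, was met, but with 5 genes on each side the shares lie within counting error. Reads running past the end therefore cannot be told apart from induction of the neighbours themselves, because the genes are too few.

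The last pattern weighed was the lower collagen and vitellogenin mRNA in affl-2. A scaling difference moves all genes alike, yet the median of the 160 listed genes minus that of all genes was −0.93 (SD over replicate numbers 0.391), which argues against scaling as the whole cause. A shift in developmental timing cannot be told apart from a direct effect without a time course. With an estimated correlation the smallest adjusted p of the molting, oocyte and sperm lists was 0.739 without heat shock (0.523 for sperm genes after it), while at the preset correlation molting genes passed without heat shock (median −0.66, adjusted p = 0.00442) and sperm genes after it (median 0.35, adjusted p = 2.7e-05). A variant linked to affl-2 or elsewhere in the mutant strain that acts on distant genes was not tested and stays open, although the 208 genes within 1 Mb of affl-2 were called about as often as other genes (14.9% and 14%).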

How the results depend on the processing

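The scaling by library size alone was chosen after the data were seen. Each left-out library leaves 2 in its group.

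Of 2904 values of named genes under alternatives 2792 stayed on their side of the threshold, 68 lost it, 44 gained it and 0 that passed turned direction, and of 2736 with 1 library left out 2614, 105, 17 and 0 did so. Values that did not pass could turn. For hsp-16 family summed, interaction of genotype and heat shock (−0.26) ranged from −1.84 to 0.23 with 1 library left out, at 0.03 and 0.23 without unheated N2 replicates 1 and 2. Among 560 list tests 468 held, 79 lost and 13 gained. The weaker rise of heat-induced genes (−0.335) depended most on how the genes were chosen. Chosen in N2 alone the median was −0.696, with 219 genes weaker and 7 stronger, and chosen in affl-2 alone it turned to 0.129, with 70 and 30. Choosing by a single genotype favours that genotype by construction. With log2 changes beyond 2 it was −0.737 (60 and 9), with a minimum count of 50 −0.493 and with library size alone −0.469, and for these the cause was not tested. DESeq2 called 216 interaction genes, including all 110. Without the low-count filter the agreement of the heat shock effects fell to 0.485. Testing for changes beyond 2-fold left 401, 265, 1.0e+02, 246 and 23 genes (heat shock in N2 and affl-2, genotype without and after it, interaction) and ended the call of affl-2 itself (−0.61), since it asks for a larger change. An estimated correlation left 6 of 63 list calls.

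The replicate numbers did not meet the bound set for pairing, a correlation above 0.1 in each of 18 pairs, as titled (12 pairs, lowest −0.293) or with unheated affl-2 replicates 1 and 2 exchanged (17 pairs, lowest 0.098). That exchange was tried because their labels carry conflicting library numbers. Libraries correlated best with their own number in 9 of 12 cases as titled and 12 of 12 exchanged. The exchanged numbers thus go with shared batches, though the bound was not met, and the main fit did not take such batches out. With the titled numbers as a block 3852 and 3910 genes changed with heat shock, 2670 and 3667 between genotypes and 125 in the interaction. With the exchange the genotype counts were 3604 and 5155 and the interaction count 221, with 17.2% higher against 6.4%. The hsp-16 sum after heat shock passed without unheated N2 replicate 2 or 3 and under DESeq2 (−2.13, adjusted p = 0.023), limma-voom (−2.12) and the exchanged block (−2.14, adjusted p = 0.0403), with adjusted p from 0.00148 to 1 over all alternatives. The cause was not tested.

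Library size alone gave 3386 and 5699 genotype calls and moved the median of all genes by −0.182 and −0.142 with heat shock and by 0.183 and 0.223 between genotypes, and moved the list medians given under it in the report toward or past 0. The higher share became 20.7% and 26.1% for heat shock (44.2% and 49.6%) and 80.8% and 85.4% for genotype (47.9% and 51.5%). Upper-quartile scaling moved the genotype shares to 61.4% and 68.7%, and fitting only the compared groups put the heated mutant at 36.3%.

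With 1 library left out the counts ranged over 2290 to 3647 and 2462 to 3277 for heat shock, 1220 to 2550 and 1475 to 3897 for genotype, and 80 to 128 for the interaction. Without heat shock the count was 1422 without N2 replicate 1, 1220 without N2 replicate 3 and 1228 without affl-2 replicate 2. After it, the count was 1763 and 1726 without N2 replicates 1 and 2, and 1475 and 1947 without affl-2 replicates 1 and 3. The median interaction ranged from −0.456 to −0.179 (lowest without unheated N2 replicate 3, highest without unheated affl-2 replicate 3), weaker genes came to at least 108 and stronger ones ranged from 11 (without heated N2 replicate 2) to 58 (without unheated affl-2 replicate 3), with 12 without unheated N2 replicate 2. Agreement ranged from 0.731 to 0.784, the affl-2 level from −0.68 to −0.51, and the hsp-16 sum from −2.19 to −1.96 after heat shock and from −2.34 to −0.27 without it, the last lacking unheated N2 replicate 3. For hsp-70, interaction of genotype and heat shock was lost without unheated affl-2 replicate 2 (adjusted p = 0.0591) or heated affl-2 replicate 2 or 3 (0.0774 and 0.0502). Depth limits what can be said of genes near 0 reads without heat, whose folds rest on few counts.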

Other observations

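The gene families in this part were tested after the data were seen, over 383 families of at least 5 genes sharing a name. Fisher's exact test takes the genes of a family as independent, so its p-values do not measure the spread between libraries. Genes that vary together make them too small. In unheated animals rpl genes, lower in affl-2, gave an adjusted p of 2.45e-16 by this test. Ribosomal proteins as a list gave 0.515 by camera with an estimated correlation.

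Nuclear receptor genes were enriched among the falls with heat shock: 90 of 203 nhr genes fell and 15 rose in N2 (24.4 falls by chance, adjusted p = 1.9e-28), and 93 fell and 17 rose in affl-2 (21.9 falls by chance, adjusted p = 1.3e-34). Glucuronosyltransferase genes fell as well, 24 of 62 ugt genes in each genotype (adjusted p = 1.4e-05 in N2), while 11 rose in N2 and 6 in affl-2. All 7 acox genes, which encode peroxisomal acyl-CoA oxidases, fell in N2 (adjusted p = 4.6e-05) and 5 in affl-2 (adjusted p = 0.0196). In N2, 35 of 130 C-type lectin (clec) genes fell too and 8 rose (adjusted p = 0.000208).

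Between the genotypes, histone genes were lower in affl-2 in 21 of 44 cases without heat shock (1 higher, median −1.2, adjusted p = 4.1e-11) and 25 after it (none higher, median −1.4, adjusted p = 1.2e-12). Most histone mRNAs lack a poly(A) tail, so their reads in these selected libraries cover an unknown part of them. Lower as well without heat shock were 13 of 16 nspc genes (median −1.63, adjusted p = 5.3e-11), 10 of 13 abu genes (median −1.39, adjusted p = 6.1e-08) and all 5 pud genes (median −5.96, adjusted p = 7.1e-05), some of which are near-identical copies. After heat shock 6 of 7 nol genes (adjusted p = 0.000209) and 6 of 11 genes of the Integrator complex (ints, adjusted p = 0.00802) were lower, and 33 of 147 fbxa genes were higher and 5 lower (14.9 by chance, adjusted p = 0.00245).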
